A study of Mus musculus with 16 samples.

How the data were processed

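Cortex RNA of 16 C57BL/6 mice was measured in 3 groups, WT saline (n = 6), KO saline (n = 5) and KO AAV (n = 5), with 1 library per animal and no pooling. Group, age, RNA integrity number and replicate number are taken from the labels, and sex and treatment duration from the deposited sample annotation. Ages ran from 12 to 12.93 months, and the RNA integrity number was 8 in WT saline replicate 3 and KO saline replicate 4 and 9.2 to 9.6 in the other libraries. Per the labels, animals were perfused with buffered saline, RNA came from frozen brain powder, and libraries were made with a QuantSeq 3' kit whose unique molecular identifiers serve to remove PCR duplicates. Per the submitters' processing notes, the authors used FastQC 0.11.5, STAR, MultiQC 1.0, R 4.2 and edgeR 3.40.2 with genome build GRCm38.p6; the counting program, its strand setting and the annotation release are not given in the sources used here.

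The authors deposited a table of raw counts per gene, whole numbers for 53801 gene identifiers, which is the input of every test unless another is named. The authors also deposited a signal table of depth-scaled counts (CPM) and, in the sample annotation, library sizes and a normalization factor per library, a ratio that multiplies the library size. Each deposited CPM signal equals the count divided by library size times factor, within rounding. Every deposited count has at most 2 significant digits, so that the 46347 values of 100 or more (17.3% of the values above 0, holding 83.1% of the counts) are rounded, by at most 5%. Column sums lie within -0.269% to 0.284% of the deposited library sizes. Total counts per library ran from 1351974 to 2119019, and the floor of 3 counts used for a gene at 0 covers counting error only.

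Genes were filtered with filterByExpr, which kept 10363, scaled with TMM, and tested in 1 edgeR quasi-likelihood fit over all 16 libraries with group as the single factor (R 4.3.3, edgeR 4.0.16, data.table package 1.17.8, limma 3.58.1, DESeq2 1.42.0). The common biological coefficient of variation was 0.181. Adjusted p are Benjamini-Hochberg values over the genes of a comparison, with a threshold of 0.05, unless a list is named. The 3 comparisons were KO saline against WT saline, KO AAV against KO saline and KO AAV against WT saline. CPM in the text are counts over TMM-scaled library totals, with SD over animals; SE are those of the fitted log2 change. A gene counted as changed back when it passed in the first 2 comparisons in opposite directions. Positions come from GENCODE M21, in which 51464 identifiers matched with their version and 53620 without it. Of the 10363 tested genes 10354 had a transcript sequence there for GC content. Symbols are those deposited with the counts, and an annotation symbol served only to match list members that the deposited symbols lacked.

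Of 35 gene lists, 31 had at least 5 tested members and were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and directional fry stood beside it; fry asks whether a list's genes move one way on balance and does not compare them with other genes. Border-associated macrophage, choroid plexus and ependyma, lymphocyte, and neutrophil and monocyte markers had under 5 tested members and were left out of these tests. Scores per library, single genes' CPM and depths were compared with two-sided exact permutation tests, and genes near Grn with Fisher's exact test. Grn was put in no list. Named genes are Grn, up to 10 called genes per direction, the 4 members of lowest p in each list, a panel of 21 genes that includes Grn, and list or panel members with a library far from the others of its group; Fam171a2 and Ctsc fall under the list rule. The lists, panel, tests, thresholds and most alternatives were fixed before the data were examined; the closing section names those added later. A first look at gene, list and component values came before the tests of explanations were written. A contrast of both knockout groups averaged against WT saline was also tried after the data were seen and is used nowhere else, since it was not among the fixed comparisons. It called 2 genes, Grn and Gfap, in edgeR (509 unadjusted), and 5 lists by camera, the 5 that changed back, or 1 with an estimated correlation.

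Recovery was computed on 100 seeded draws that chose genes on 3 KO saline and 3 WT saline libraries and measured them on the other 2 and 3 and all KO AAV libraries. Alternatives covered scaling, filters, DESeq2, limma-voom, limma on the deposited CPM signal, covariates, a replicate block, other list tests, and leaving out each library. The fit was tested on simulated data of the same depth, spread and group sizes, with 200 changed genes of 10363 in each of 4 runs: it found 24.3%, 72% and 97.3% of genes changed 1.5, 2 and 4-fold in KO saline against WT saline, 17.5%, 67.9% and 97.3% in KO AAV against KO saline, and 23.1%, 72.4% and 98.1% in KO AAV against WT saline. Of its calls 3.65%, 5.82% and 5.65% were false, and 4.02%, 6.16% and 5.99% with the simulated counts rounded as the deposited ones are. Camera found a list of 26 genes shifted by 0.5 on the log2 scale in 4 of 4 runs of each comparison and called 0 unshifted lists. The simulated genes were independent of one another, so these runs do not measure how often camera falsely calls lists whose genes vary together. They also lack the spread shared across genes that the first principal component of the real libraries shows. The shares of false gene calls hold for data without that shared spread.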

Results

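Polyadenylated RNA from the cortex of 16 mice of about 12 months was counted gene by gene with a 3' sequencing method, 1 library per animal. Wild-type mice given saline (WT saline, n = 6, 3 males and 3 females) stood beside mice lacking Grn, the progranulin gene, given saline (KO saline, n = 5, 4 males and 1 female). A further set of Grn knockout mice (KO AAV, n = 5, 3 males and 2 females) had received a liver-targeting adeno-associated virus into the tail vein 8 months earlier, at a dose of 300000000000 vector genomes. That virus encodes human progranulin fused to 8D3, a single-chain antibody fragment against the mouse transferrin receptor. Total counts were 1821110 ± 182193 (mean ± SD, n = 6) in WT saline, 1497800 ± 162617 (n = 5) in KO saline and 1767670 ± 96838 (n = 5) in KO AAV, with a range over all libraries from 1351974 to 2119019. KO saline libraries were the smallest group on average, by a two-sided exact permutation test against WT saline (p = 0.0173) and against KO AAV (p = 0.0238). Mitochondrial transcripts took 23.4 ± 1.42% of the counts in WT saline, 25.5 ± 2.69% in KO saline and 23.2 ± 1.65% in KO AAV (SD). These differences did not pass the same exact test (p = 0.126 for KO saline against WT saline, 0.175 for KO AAV against KO saline, 0.816 for KO AAV against WT saline). Counts of Xist and Ddx3y matched the recorded sex of all 16 animals.

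Grn itself (ENSMUSG00000034708, chromosome 11, 102430315 to 102437048, GRCm38) had 226 counts over the 6 WT saline libraries, 16 to 67 in each, or 20.6 ± 9.25 depth-scaled counts (CPM, mean ± SD, n = 6). No count of Grn was found in any of the 5 KO saline or 5 KO AAV libraries. Taking 3 counts over a group's libraries as the floor that a count of 0 allows, Grn was at least 49.9-fold lower in KO saline (edgeR adjusted p = 5.09e-04) and at least 61.4-fold lower in KO AAV (adjusted p = 5.62e-04) than in WT saline. With both knockout groups at 0, no fold between them is given. These counts are of mouse Grn in cortex, whereas the virus carries human progranulin for expression in liver, so they do not measure the transgene.

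The first comparison, KO saline against WT saline, asked how the cortex of a progranulin-deficient mouse differs at this age. Gfap, the intermediate filament of astrocytes, rose from 21.3 ± 6.17 CPM in WT saline (SD, n = 6) to 71.0 ± 15.5 CPM in KO saline (n = 5), a log2 change of 1.73 (SE 0.18; adjusted p = 3.86e-05). Clec7a, a pattern-recognition receptor that marks activated microglia, rose 8.32-fold, from 1.09 ± 0.810 to 9.69 ± 2.24 CPM (log2 change 3.06, SE 0.40; adjusted p = 5.09e-04). Its counts were low, 12 over the 6 WT saline libraries (1 to 5 each) and 70 over the 5 KO saline libraries (9 to 17 each), so that fold is rough. The microglial lysosomal protease gene Ctss rose 1.56-fold, from 216 ± 16.9 to 337 ± 29.0 CPM (log2 change 0.64, SE 0.09; adjusted p = 0.00221). Lyz2, the lysozyme gene of myeloid cells, rose 3.28-fold, from 11.7 ± 4.97 to 39.2 ± 17.2 CPM (log2 change 1.71, SE 0.31; adjusted p = 0.0277). In each of these 4 genes all 5 KO saline libraries lay above all 6 WT saline libraries (two-sided exact permutation p = 0.002165 for each, the smallest that 5 against 6 allows). These 4 genes were named for their low p in the same libraries, so the exact p is not separate evidence for them. Their loci are chromosome 11, 102887336 to 102900912 (Gfap, ENSMUSG00000020932), chromosome 6, 129461591 to 129472779 (Clec7a, ENSMUSG00000079293), chromosome 3, 95526786 to 95556403 (Ctss, ENSMUSG00000038642) and chromosome 10, 117277331 to 117282321 (Lyz2, ENSMUSG00000069516).

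With Grn these made 5 genes past an adjusted p of 0.05 among 10363 tested, 4 higher and 1 lower in KO saline. The count was 16 with no count filter and 2 with the males alone. In edgeR 426 genes had an unadjusted p under 0.05 where chance alone would give 518. Of the 21 panel genes fixed in advance, 16 were abundant enough to test. Of these 8 passed when adjusted over the list alone, which adds Tyrobp, Ctsz, Cd68 and C4b to Grn, Clec7a, Lyz2 and Gfap. Tyrobp, the signalling adaptor of Trem2, was at a log2 change of 0.59 (SE 0.14), Cd68, a lysosomal protein of phagocytes, at 0.95 (SE 0.38), and C4b, a complement component, at 0.92 (SE 0.35). Over all genes their adjusted p were 0.565, 0.994 and 0.994. Microglial genes below the count filter were given exact permutation tests on CPM, unadjusted: Gpnmb had 27 counts in WT saline and 47 in KO saline (p = 0.00866), Lgals3 had 3 and 15 (p = 0.00433), and Cst7 had 4 and 13 (p = 0.0195). Serpina3n, an acute-phase gene of reactive astrocytes, had 17 and 19 (exact p = 0.0866), and Itgax had 0 and 2 (exact p = 0.182). The Lyz2 call was lost without WT saline replicate 1 (adjusted p = 0.125), 2 (0.0833), 3 (0.0865) or 5 (0.108), and without KO saline replicate 1 (0.159), 4 (0.129) or 5 (0.0817). It held in 21 of 37 alternative settings (adjusted p from 1.19e-11 to 0.273). With the males alone, a setting chosen after seeing the data, the calls of Clec7a (log2 change 2.59; over 35 settings adjusted p from 1.17e-07 to 0.424, the highest being this one), Ctss (0.63; over 37 settings 1.06e-09 to 0.608, again the highest) and Lyz2 (2.11; adjusted p = 0.175) were lost. Gfap kept its call there (2.16). With the replicate number as a block the calls of Ctss (0.62, adjusted p = 0.0585) and Lyz2 (1.82, adjusted p = 0.0882) were lost. How the counting treated reads shared by Lyz2 and its paralog Lyz1, or by C4b and C4a, is not given in the sources used here.

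**Figure D1:**
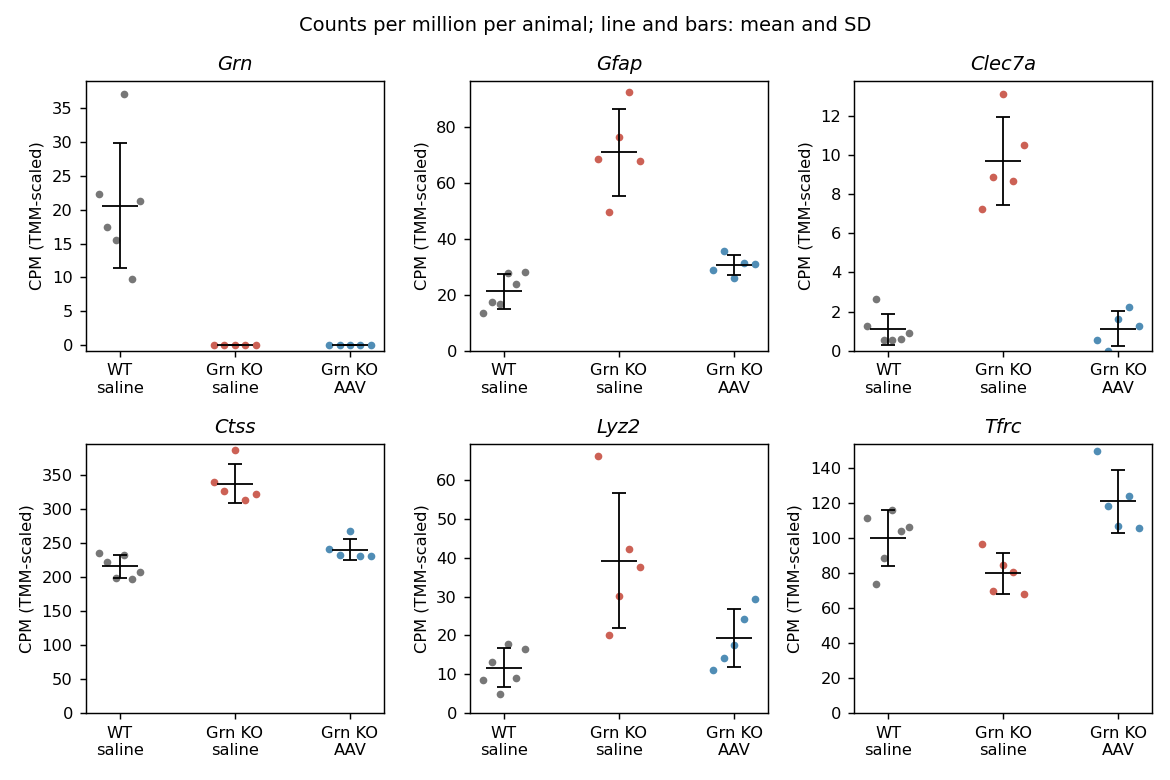
Depth-scaled counts (CPM, y axis, linear, TMM-scaled) of 6 genes in each animal of the 3 groups (x axis; points are animals, n = 6, 5 and 5; line and bars are mean and SD). Every KO saline animal lies above every WT saline and KO AAV animal for Gfap (lowest KO saline value 49.7 CPM) and Clec7a (lowest 7.26 CPM), while Grn is at 0 in both knockout groups.

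Among 31 gene lists with at least 5 tested members, 6 were higher in KO saline than in WT saline by camera with a preset inter-gene correlation, and none was lower. Without 1 library that count ran from 5 to 11 (11 without WT saline replicate 4, 10 without KO saline replicate 2), and with the males alone it was 11. Disease-associated microglia genes rose as a group (adjusted p = 2.78e-12), with 24 of 26 tested members at a positive log2 change. Of them 2 passed over all genes (Clec7a and Lyz2) and 3 when adjusted over the list alone (with Tyrobp), and none fell. Reactive astrocyte genes rose (adjusted p = 1.64e-07; 11 of 13 positive), Gfap passing over all genes and Gfap, Vim, Ggta1 and C4b when adjusted over the list alone. Vim, an intermediate filament, was at 0.59 (SE 0.14). Complement genes were positive in 7 of 7 (adjusted p = 1.32e-05), 0 passing over all genes, with C1qc at 0.54 (SE 0.16) and C4b among those that passed when adjusted over the list alone. Lysosome genes rose as a group (adjusted p = 1.32e-05; 39 of 51 positive), with Ctss passing over all genes and Ctss and Ctsc, the dipeptidyl peptidase gene, when adjusted over the list alone. The lysosome score of KO saline replicate 3 stood apart (0.2365, others 0.0418 to 0.0824), and without that library the adjusted p of the list was 0.0197. Lipa, the lysosomal acid lipase gene, was at -0.64 (SE 0.22), against the direction of that list, and did not pass. Pan-microglia and macrophage genes rose too (adjusted p = 2.44e-04; 13 of 16 positive), Ctss passing in both ways of adjusting.

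Those 5 lists were also called with an estimated correlation (adjusted p from 1.53e-04 to 0.0317) and by fry, and each kept its call without any 1 of the 16 libraries. The remaining list, markers of hippocampus and thalamus, had 5 of 6 positive members and no member that passed, with Prkcd at 0.45 (SE 0.22) and Zic1 at 0.38 (SE 0.22). Its adjusted p was 0.0482, and adjusted p = 0.119 with an estimated correlation. Without KO saline replicate 1, 3 or 5, WT saline replicate 3, 5 or 6, or KO AAV replicate 2, that call was lost (adjusted p up to 0.192). The lists share members. For example, 6 tested genes are both lysosomal and disease-associated microglial, C4b is a complement and a reactive astrocyte gene, and Ctss a lysosomal and a pan-microglial one. Astrocyte markers (adjusted p = 0.440, median log2 change 0.05), homeostatic microglia markers (0.0833, median 0.08), endothelial markers (0.828, median 0.01) and oligodendrocyte and myelin genes (0.107, median -0.08) did not pass. In 8 of the 31 lists, none of them called, the mean, median and camera direction were not all of the same sign, erythrocyte genes for example being called Down at a mean of +0.11.

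Per animal, the score of disease-associated microglia genes (mean log2 CPM of 26 members less each gene's mean) was -0.17 ± 0.11 in WT saline (SD, n = 6) and 0.25 ± 0.05 in KO saline (n = 5). The difference of 0.42 had a two-sided exact permutation p of 0.002165, the smallest possible, and 0.0065 after adjustment over 3 comparisons.

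**Figure D2:**
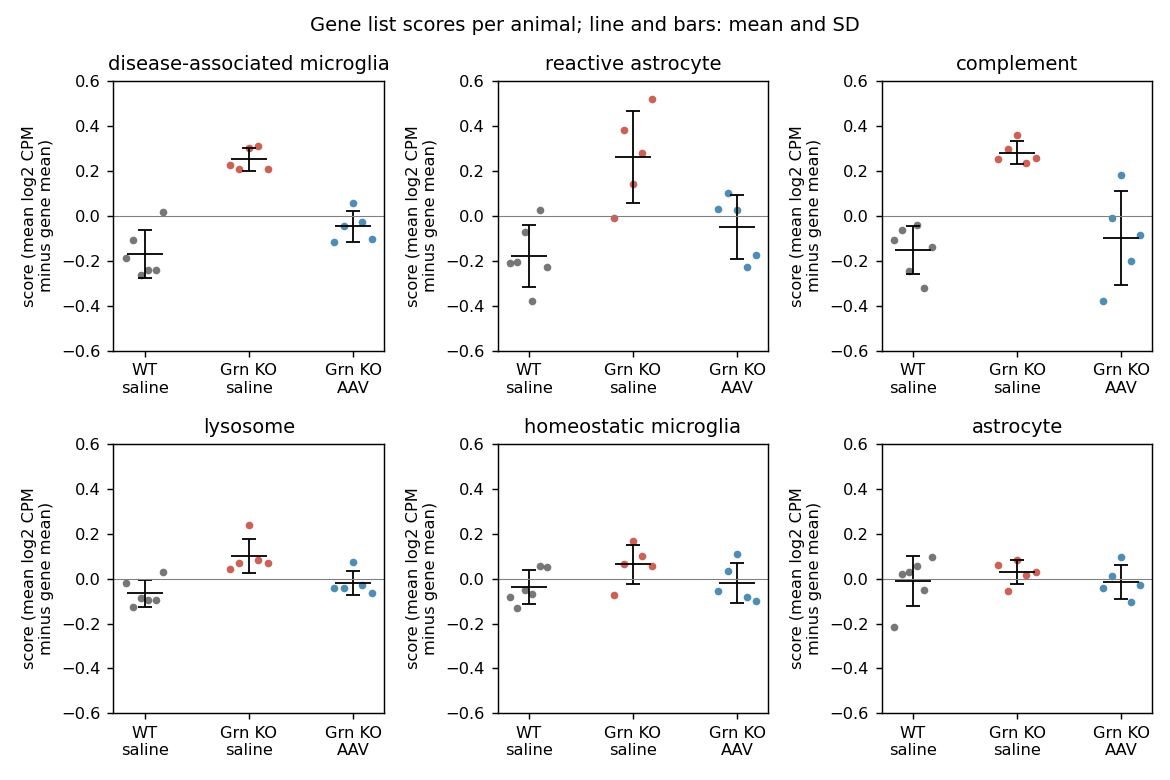
Scores of 6 gene lists (y axis, mean log2 CPM of the members less each gene's mean over all 16 libraries) in each animal of the 3 groups (x axis; points are animals, n = 6, 5 and 5; line and bars are mean and SD). Disease-associated microglia scores average -0.17 in WT saline, 0.25 in KO saline and -0.05 in KO AAV, while the astrocyte score averages between -0.01 and 0.03 in the 3 groups.

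The second comparison, KO AAV against KO saline, asked what the liver-targeting virus changed in the knockout cortex. Gfap fell 2.32-fold, from 71.0 ± 15.5 CPM in KO saline (SD, n = 5) to 30.7 ± 3.49 CPM in KO AAV (n = 5; log2 change -1.21, SE 0.19, adjusted p = 0.0086). Clec7a fell 8.14-fold, from 9.69 ± 2.24 to 1.13 ± 0.885 CPM (log2 change -3.02, SE 0.43, adjusted p = 0.00454). Its KO AAV values ran from 0 to 2.26 CPM, near the floor, so the size of that fold is rough. All 5 KO AAV libraries lay below all 5 KO saline libraries for both genes (two-sided exact permutation p = 0.007937 each, the smallest that 5 against 5 allows). Here too the exact p is not separate evidence, as the same libraries gave the calls. For Ctss the means were 337 ± 29.0 and 240 ± 15.5 CPM, again without overlap between the 5 and 5 libraries, but the log2 change of -0.49 (SE 0.10) had an adjusted p of 0.231 in edgeR. DESeq2 called Ctss lower (adjusted p = 7.97e-04), as did edgeR with the first residual component (0.0121) or the first principal component (0.0278) as a term, while limma-voom did not (0.188; over all settings 7.97e-04 to 1.00). Lyz2 was at -1.03 (SE 0.31; adjusted p = 1.00), and passed with no count filter (0.0141). Tfrc, the gene of the receptor that 8D3 binds, was at 0.60 (SE 0.14; unadjusted p = 4.00e-04, adjusted p = 1.00), with 121 ± 17.9 CPM in KO AAV and 80.1 ± 11.8 CPM in KO saline and no overlap between the libraries.

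Gfap and Clec7a were the 2 genes that passed among 10363, both lower. At an unadjusted p under 0.05 there were 258 genes, where chance alone would give 518. The count of genes that passed was 4 with no count filter or with the first residual component as a term. It was 1 with mean CPM of at least 5 or with thinned libraries. Males alone, limma on log2(deposited CPM + 0.25) and the replicate number as a block each gave 0. In the fixed panel 9 genes passed when adjusted over the list alone: Tfrc above 0, and Clec7a, Gfap, Tyrobp (-0.50, SE 0.15), Apoe (-0.27, SE 0.10), Ctsz (-0.52, SE 0.21), Lyz2, C1qa (-0.68, SE 0.22) and C4b (-1.04, SE 0.37) below. Below the count filter, Gpnmb had 47 counts in KO saline and 28 in KO AAV (exact permutation p = 0.0397, unadjusted), Lgals3 had 15 and 4 (exact p = 0.0397), Cst7 had 13 and 4 (exact p = 0.0476), and Serpina3n had 19 and 22 (exact p = 0.722). Ctsc, one of the lysosomal genes above, was at -0.08 (SE 0.21), with 18.1 ± 4.97 CPM in KO saline and 17.2 ± 4.14 CPM in KO AAV. The Gfap call was lost without KO AAV replicate 1 (log2 change -1.18, adjusted p = 0.0651), 3 (-1.15, 0.0715) or 4 (-1.21, 0.051), without KO saline replicate 4 (-1.08, 0.0729), and without both libraries of RNA integrity 8 (-1.08, 0.081). Over 37 settings Gfap kept the call in 29 (adjusted p from 1.94e-06 to 0.171), and over 35 settings Clec7a kept it in 32. Fitting by limma on log2(deposited CPM + 0.25) and using the males alone ended both calls, at an adjusted p of 0.0824 and 0.171. The log2 changes there were -3.17 and -3.56 for Clec7a and -1.16 and -1.24 for Gfap. Using the replicate number as a block also ended both calls, at -3.01 for Clec7a (adjusted p = 0.059) and -1.18 for Gfap (adjusted p = 0.0512).

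By camera 8 lists were lower and 2 higher in KO AAV than in KO saline. Disease-associated microglia genes fell as a group (adjusted p = 8.94e-07; 20 of 26 negative), Clec7a alone passing over all genes and 3 members (Clec7a, Tyrobp and Lyz2) when adjusted over the list alone. Spp1, the osteopontin gene, at 0.33 (SE 0.27), and Csf1 at 0.13 (SE 0.33) were among the positive members. Reactive astrocyte genes fell (adjusted p = 5.73e-05; 10 of 13 negative), Gfap passing over all genes and Gfap, Vim (-0.49, SE 0.15) and C4b when adjusted over the list alone. Complement genes fell (adjusted p = 2.76e-04; 6 of 7 negative), 0 passing over all genes and C1qa, C1qc (-0.43, SE 0.17) and C4b when adjusted over the list alone. These 3 lists were also called with an estimated correlation (adjusted p = 0.003, 0.0273 and 0.0213).

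Other lists passed with the preset correlation but not with an estimated one. Lysosome genes fell in that sense (39 of 51 negative; adjusted p = 8.92e-04, and adjusted p = 0.078 with an estimated correlation), 0 passing over all genes and Ctss when adjusted over the list alone. Without KO saline replicate 3 the adjusted p of the lysosome list was 0.0426 with the preset correlation. Interferon response genes (11 of 13 negative; 0.00347, and adjusted p = 0.0728 with an estimated correlation) included Rtp4 at -0.84 (SE 0.32) and Lgals3bp at -0.83 (SE 0.34), neither of which passed. Antigen presentation genes (5 of 6 negative; 0.00347, and adjusted p = 0.0577 with an estimated correlation) included Tapbp at -0.63 (SE 0.28) and B2m at -0.29 (SE 0.15), with no member that passed. Pan-microglia and macrophage genes (11 of 16 negative; 0.0372, and adjusted p = 0.078 with an estimated correlation) had 0 members past the threshold over all genes and Ctss when adjusted over the list alone. This call was lost without KO AAV replicate 1, 2 or 5, or KO saline replicate 2, 3 or 5 (adjusted p up to 0.126). Mitochondrially encoded genes (7 of 8 negative; 2.76e-04, and adjusted p = 0.127 with an estimated correlation) included mt-Nd4 at -0.41 (SE 0.17), and none passed. That gene stood at 73410 CPM in KO saline replicate 1 against 33350 to 42460 CPM in the rest of its group.

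Oligodendrocyte precursor markers were higher (9 of 12 positive; 0.0147, and adjusted p = 0.0577 with an estimated correlation), Vcan at 0.51 (SE 0.25) and Olig1 at 0.33 (SE 0.17) not passing. That call was lost without KO saline replicate 2 or 5 (adjusted p up to 0.0759). Erythrocyte genes were positive in 6 of 6 (0.0486, and adjusted p = 0.310 with an estimated correlation), with Hbb-bt at 0.45 (SE 0.43) and Hbb-bs at 0.30 (SE 0.46), a pair of close paralogs. That call stood without KO saline replicate 1 or 3 or KO AAV replicate 4 and was lost without any of the other 13 libraries (adjusted p up to 0.611). Iron and transferrin receptor genes did not pass camera (8 of 13 positive; 0.0904), but fry called them higher (adjusted p = 0.0335), and their score differed by 0.13 (two-sided exact permutation p = 0.0238, and 0.0357 adjusted over 3 comparisons), Tfrc being the member that passed when adjusted over the list alone. Nor was there a call for homeostatic microglia (0.122), astrocyte (0.235) or endothelial markers (0.508). The synapse, striatum and autophagy lists, none called, had a mean, median and camera direction that were not all of the same sign.

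The disease-associated microglia score was -0.05 ± 0.07 in KO AAV (SD, n = 5) and 0.25 ± 0.05 in KO saline (n = 5), a difference of -0.30 (two-sided exact permutation p = 0.007937, the smallest possible, and 0.0119 adjusted over 3 comparisons).

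**Figure D3:**
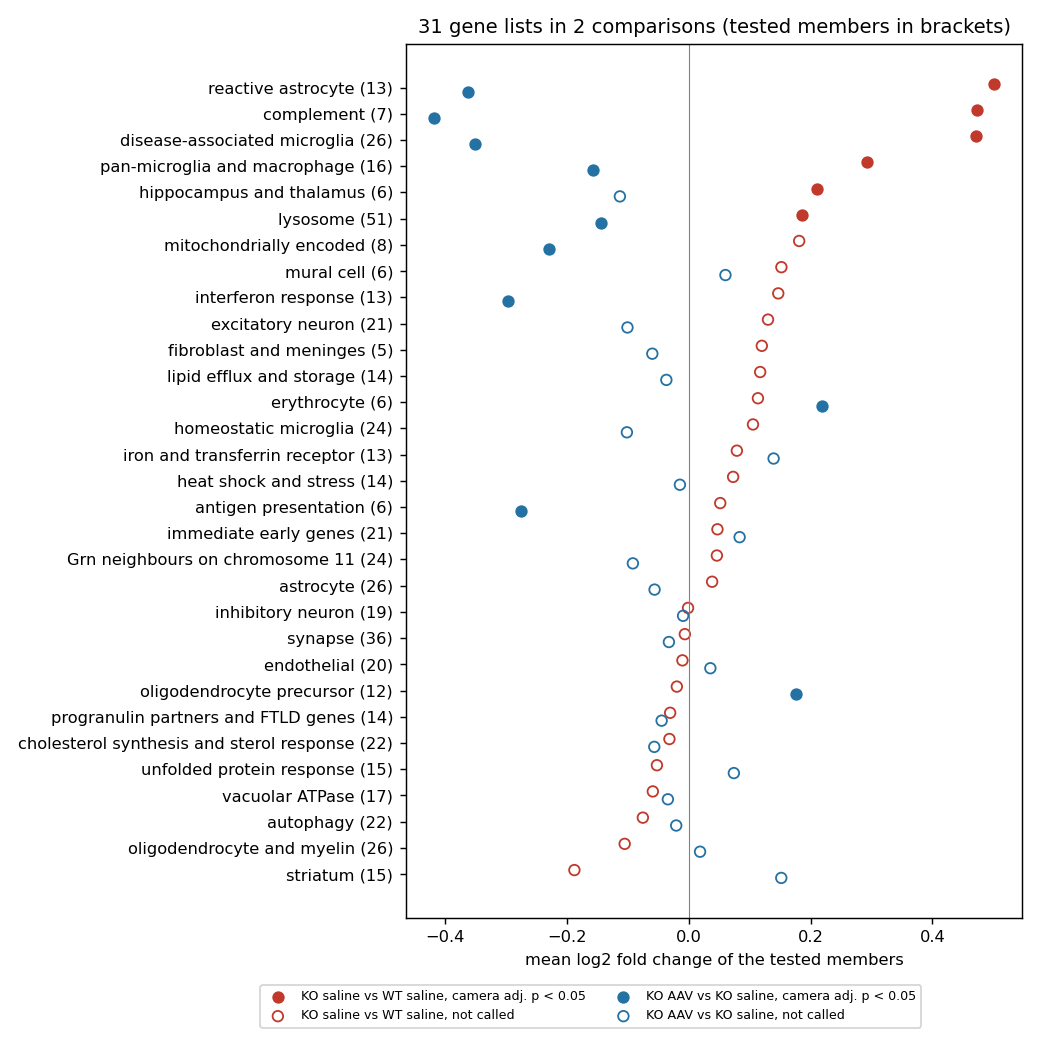
Mean log2 fold change of the tested members (x axis) of each of 31 gene lists (y axis, tested members in brackets) in KO saline against WT saline and in KO AAV against KO saline; filled points passed camera at the preset correlation and open points did not. The lists of disease-associated microglia, reactive astrocytes, complement, lysosome and pan-microglia lie right of 0 in the first comparison and left of 0 in the second.

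Taking both comparisons, 2 genes changed in the knockout and changed back under the virus, Gfap and Clec7a. So did 5 lists with the preset correlation: lysosome, disease-associated microglia, pan-microglia and macrophage, complement and reactive astrocyte. With an estimated correlation or by fry 3 of them did, since the lysosome and pan-microglia lists were then not called in KO AAV against KO saline (adjusted p = 0.078 for each with an estimated correlation, and 0.0855 or more by fry). Without KO AAV replicate 1, 3 or 4 or KO saline replicate 4 the count of genes was 1, Clec7a. It was also 1 with mean CPM of at least 5, with thinned libraries or without both libraries of RNA integrity 8, and 4 with no count filter. Males alone, limma on log2(deposited CPM + 0.25) and the replicate number as a block each gave 0. Both comparisons use the same KO saline libraries, so a group of high KO saline values alone would give changes back. In 40 simulated data sets without any effect, that of the knockout included, 0 genes and 0 lists changed back. Hardly any gene and no list was called there in KO saline against WT saline, so little could change back. The simulations do not show how often genes that differ in the knockout would seem to change back through the shared libraries. Genes were drawn independently of one another there, so the 0 lists do not measure chance for lists whose genes vary together. The 2 comparisons taken as independent would give 7.72e-04 genes and 1.55 lists. With the KO saline libraries split so that each comparison used its own part (20 splits), 0 to 2 genes changed back, Clec7a in 10 splits and Gfap in 7, and lists did so in unequal numbers of splits: disease-associated microglia in 19, complement in 18, reactive astrocyte in 15, lysosome in 4 and pan-microglia and macrophage in 3. Recovery, the share of the knockout difference in log2 CPM that was absent in KO AAV, was 0.680 for Gfap, 1.00 for Clec7a, 0.756 for Ctss and 0.580 for Lyz2 when the same libraries chose and measured the genes. With genes chosen on 3 KO saline and 3 WT saline libraries and measured on the other 2 and 3, the median over draws was 0.797 (range 0.153 to 1.29), from the 30 of 100 draws that chose any gene, Gfap in 27 of them. The most genes chosen in a draw were 668, so single draws are unstable.

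The third comparison, KO AAV against WT saline, asked what difference was left after treatment. Gfap stood at 30.7 ± 3.49 CPM in KO AAV (SD, n = 5) and 21.3 ± 6.17 CPM in WT saline (n = 6), a log2 change of 0.52 (SE 0.19; unadjusted p = 0.0132, adjusted p = 0.881), with 4 of 5 KO AAV libraries above all WT saline libraries. In the 3 males of each group Gfap ran from 26.2 to 35.6 CPM in KO AAV and from 13.6 to 17.5 CPM in WT saline. In females it ran from 31.1 to 31.6 CPM in KO AAV (n = 2) and from 23.9 to 28.2 CPM in WT saline (n = 3). The log2 change of 0.52 pools the sexes, as does the Gfap recovery of 0.680 above. Clec7a was at 0.03 (SE 0.59) and Ctss at 0.16 (SE 0.09), and Lyz2 was at 0.69 (SE 0.32; adjusted p = 0.881). Ctsc, a lysosomal peptidase gene, was at 17.2 ± 4.14 CPM in KO AAV and 8.96 ± 1.61 CPM in WT saline (log2 change 0.93, SE 0.22; unadjusted p = 2.84e-04, adjusted p = 0.881), with all 5 KO AAV libraries above all 6 WT saline libraries. It passed when adjusted over the list alone (0.0145, 51 lysosome genes). Slc39a14, a metal ion transporter gene, was at 1.26 (SE 0.40; adjusted p = 0.881).

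In edgeR 417 genes had an unadjusted p under 0.05, where chance alone would give 518. Grn was the 1 gene that passed there, as it was by DESeq2 and limma-voom. The count was 2 with no count filter, Fam171a2 being added, and 33 with the first residual component as a term, Ctsc and Fam171a2 among them. That component by construction does not differ between groups and takes up spread within them. Fitted group differences can still shift, that of Fam171a2 from -0.76 to -0.67. In the fixed panel Grn alone passed when adjusted over the list alone. Of 31 lists 0 passed camera, with 7 at an unadjusted p under 0.05 (3 with an estimated correlation). The fry test called 2 as higher, oligodendrocyte precursor markers (adjusted p = 0.0298; 8 of 12 positive) and iron and transferrin receptor genes (0.0244; 10 of 13 positive). Disease-associated microglia genes had a camera adjusted p of 0.160 (17 of 26 positive), with Spp1 at 0.74 (SE 0.26), Csf1 at 0.82 (SE 0.32) and Clec7a at 0.03. Complement genes (0.654) and reactive astrocyte genes (0.238) did not pass either. In all, 5 lists without a call, complement and homeostatic microglia among them, had a mean, median and camera direction not all of the same sign. Without WT saline replicate 2 camera called 6 lists, without WT saline replicate 4 it called 3, and without KO AAV replicate 2 or 3 it called 1. It called 1 with mean CPM of at least 5, with thinned libraries or with the first principal component as a term, 2 with the GC trend removed and 4 with the males alone. The disease-associated microglia score was -0.05 ± 0.07 in KO AAV (n = 5) and -0.17 ± 0.11 in WT saline (n = 6), a difference of 0.12 (two-sided exact permutation p = 0.0541). That exact p was 0.0476 without WT saline replicate 2, 0.0159 without 6, and 0.0429 and 0.0286 without KO AAV replicates 1 and 5. Leaving out a KO saline library alters only the genes tested and their scaling here. The exact p was then 0.0433, 0.0476, 0.0433, 0.0346 and 0.0346 for KO saline replicates 1 to 5.

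Genes around the targeted locus were compared with the rest of the genome, since both knockout groups carry the same altered locus. Gfap lies 450.3 kb from Grn and was the 1 called gene of 126 tested within 5 Mb of Grn (Grn left out), against 3 of 10227 elsewhere, in KO saline against WT saline (two-sided Fisher's exact p = 0.0478). With windows of 2 and 10 Mb the exact p was 0.0237 and 0.0700. In KO AAV against WT saline 0 genes near Grn passed in edgeR, and 11 of 126 had an unadjusted p under 0.05 (8.73%, against 3.96% elsewhere; Fisher's exact p = 0.018, and 0.0032 within 2 Mb and 0.0899 within 10 Mb). In KO saline against WT saline 9 of 126 had one (7.14%, against 4.06% elsewhere; Fisher's exact p = 0.106). Fam171a2, whose annotated 3' end overlaps that of Grn by 68 bases on the opposite strand, was at 82.2 ± 41.9 CPM in WT saline (n = 6), 45.4 ± 22.8 in KO saline (n = 5) and 48.6 ± 13.1 in KO AAV (n = 5). Its log2 changes against WT saline were -0.87 (SE 0.31) and -0.76 (SE 0.31), with adjusted p of 0.994 and 0.881. With no count filter it passed in both (adjusted p = 1.65e-04 and 0.0432). The strand setting of the counting is not given in the sources used here, so Grn reads counted as Fam171a2 in WT saline are not excluded as a part of these differences.

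**Figure D4:**
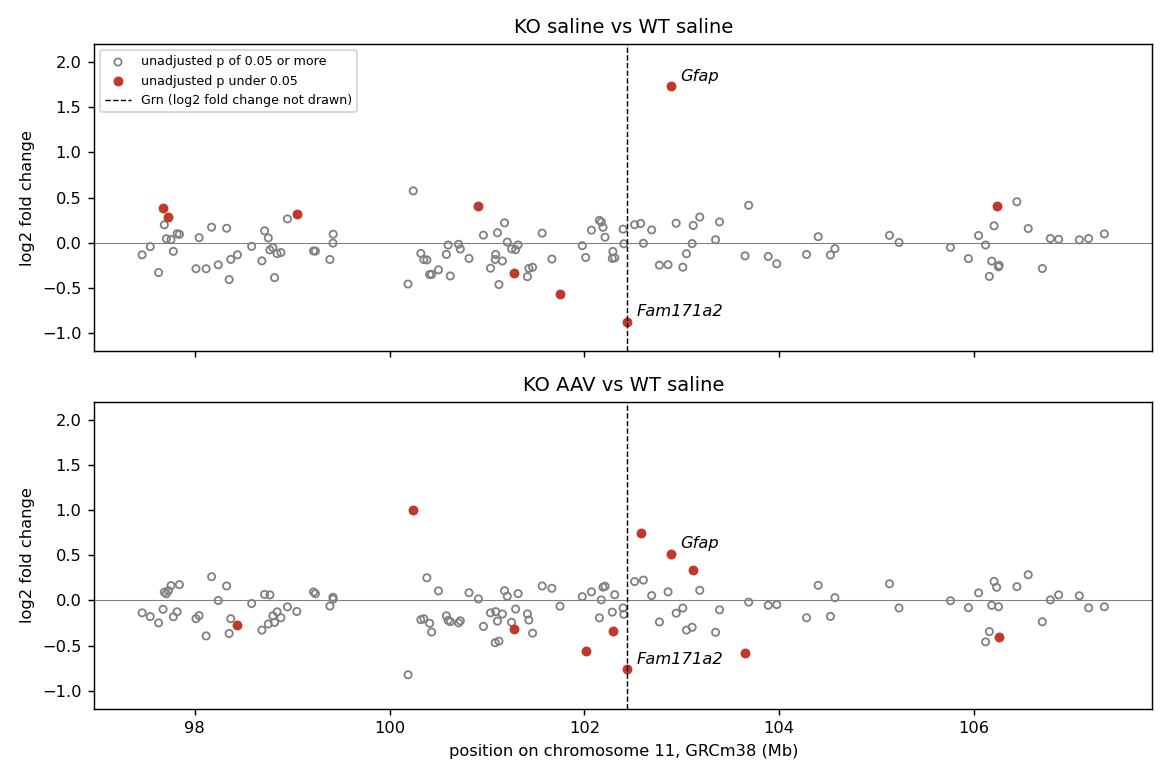
Log2 fold change against WT saline (y axis) of the tested genes within 5 Mb of Grn along chromosome 11 (x axis, GRCm38, Mb), in KO saline above and KO AAV below. Red points had an unadjusted p under 0.05, grey open points did not, and the dashed line marks Grn. Gfap stands at 1.73 in KO saline and 0.52 in KO AAV, and Fam171a2 at -0.87 and -0.76.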

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

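Chosen only after the result was seen were the tests of linked sequence, astrocyte number and depth for Gfap, every test of the first principal component, and those of endothelial RNA and of low KO saline values for Tfrc; the other tests of this part were set before their own values were seen. A first look at the data had by then shown the reactive astrocyte list to pass with Gfap in it, and the rule for residual blood was changed after its value was seen. As first written, any r below 0 argued against blood, and the stricter rule moved that test from against to open.

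In 210 group-wise checks of genes, scores and depths 15 values, from a part of the libraries, stood apart from the rest of their group, where chance flags about 1 in 20 groups, or 10.5 (12 of 171 for genes with 8.55 by chance, 3 of 33 for scores with 1.65, 0 of 6 for depths). Among microglial and lysosomal genes, Clec7a was at 2.649 CPM in WT saline replicate 2 (others 0.553 to 1.24), Itgax at 0.5355 CPM in KO AAV replicate 1 (1 count, others 0), and Ctss at 267 CPM in KO AAV replicate 3 (others 230.5 to 241). Ctsc stood at 26.56 CPM in KO saline replicate 5 (others 14.5 to 17.8). Lgals3bp was at 14.78 CPM in WT saline replicate 6 (others 5.54 to 7.98), and Tapbp, of the antigen loading complex, at 13.85 CPM in WT saline replicate 4 (others 6.14 to 8.85). The haemoglobin gene Hbb-bt was at 60.87 CPM in WT saline replicate 3 (others 18 to 30.5). Among mitochondrial transcripts mt-Nd4 was at 73410 CPM in KO saline replicate 1 (others 33350 to 42460) and mt-Nd2 at 13920 CPM in KO AAV replicate 1 (others 18610 to 19940). Prkcd was at 39.04 CPM in WT saline replicate 1 (others 15.7 to 21.5), and the myelin gene Mog at 44.32 CPM in KO AAV replicate 3 (others 21.2 to 27.7). The lysosome score was 0.2365 in KO saline replicate 3 (others 0.0418 to 0.0824) and 0.07314 in KO AAV replicate 3 (others -0.0636 to -0.0288), and the interferon response score was 0.08102 in KO AAV replicate 1 (others -0.21 to -0.127). A test of whether each effect differed between males and females gave 0 genes in edgeR in all 3 comparisons, the one tool used for it, with 504, 484 and 184 genes at an unadjusted p under 0.05. KO saline has 1 female, so the first 2 of these rest on a single animal for that group and say little about a sex difference.

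Gfap was higher in KO saline and lies near the targeted locus, so linked sequence, cell number and depth were weighed against reactive astrocytes. Sequence linked to Grn would act alike in both knockout groups, yet Gfap was lower in KO AAV than in KO saline by a log2 change of -1.21 (SE 0.19), which argues against it as the whole cause; the 0.52 (SE 0.19) left against WT saline keeps a part open. More astrocytes would raise their markers by as much as Gfap, but the median of 26 astrocyte genes was 0.0526. With all libraries thinned to the smallest total Gfap was still at 1.74, which argues against lower depth as the cause. The reactive astrocyte list without Gfap was higher in KO saline (camera p = 8.84e-06, and 0.0061 with an estimated correlation). A reactive state of astrocytes would give this, but it stays a hypothesis, with part of the linked sequence left open. Explanations other than these were not weighed. Markers of hippocampus and thalamus, described above, were also called higher in KO saline, a call that several single libraries decided.

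Libraries of every group spread along the first principal component, which held 33.9% of the variance and did not part the groups (exact permutation p = 0.580, 0.627 and 0.199 for the 3 comparisons). Gene loadings on it correlated across genes with the GC share of the last 500 bases (Spearman rho -0.41 over 10354 genes, which are not independent replicates), so a GC-related step of library preparation may contribute. It is not the whole cause, since 30.5% of the variance stayed on the first component after the GC trend was removed in each library. Low RNA integrity would place both libraries of RIN 8 near an end, but the one nearer to an end ranked 11 of 16. No biological explanation of this spread was tested. The score of striatum markers varied widely between animals, with an SD of 0.918 in WT saline, 0.242 in KO saline and 0.744 in KO AAV. For astrocyte markers the SD were 0.112, 0.053 and 0.074. Striatum scores did not differ between the groups (exact permutation p = 0.881, 0.992 and 0.900 for the 3 comparisons), and their relation to the component was not tested.

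Tfrc, whose product is the target of 8D3, was higher in KO AAV than in KO saline by 0.60 (SE 0.14; adjusted p = 1.00, 0.00213 over the panel and 0.0052 over the iron list alone), with 5 of 5 KO AAV libraries above all KO saline libraries. More endothelial RNA would raise the endothelial list alike, but its median was 0.0447, and with the GC trend removed Tfrc was still at 0.56 (unadjusted p = 0.00158), which argues against a GC trend as the cause. Residual blood cannot be told apart: over 16 libraries the deviations of Tfrc and of the erythrocyte score from their group means had r = -0.0643 (permutation p = 0.826; rho 0.0882, permutation p = 0.764; r = -0.164 without the 2 farthest libraries), which lies within its spread of 0. Whether KO saline was low or KO AAV high cannot be told apart either, as Tfrc was at 0.27 (SE 0.13) in KO AAV against WT saline and -0.33 (SE 0.14) in KO saline against WT saline. An effect of the virus or its product on Tfrc stays an open hypothesis; the iron and transferrin receptor list without Tfrc had a camera p of 0.21.

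Other splits of the libraries into groups of the same sizes were run 100 times for each comparison, the real split included. Chance is not excluded for the count of 5 genes in KO saline against WT saline: 5 of 100 splits gave as many, the highest of the others 1883, while 94 gave 0 in edgeR. This concerns the count and not each gene, as Grn, at 0 counts in every knockout library, is among the 5. The 4 other splits that gave over 20 genes all parted the libraries along the first principal component (exact permutation p from 0.00649 to 0.0303, against 0.580 for the real one), which points to that structure of the samples. Nor is chance excluded for the 6 lists of that comparison, since 18 of 100 splits gave as many and the highest other gave 13; which lists were called was not part of this count. For KO AAV against KO saline fewer than 5 of 100 splits, the limit set beforehand, gave as many. Its 2 genes were reached by 2 of 100 splits (highest other 229, in a split that also parts the first component, exact p = 0.00794). Its 10 lists were reached by 1 of 100, the real one (highest other 9). That margin was narrow, as the real count was 7 without KO saline replicate 5 and 3 with an estimated correlation. The splits were run at the preset correlation alone. They set the number of lists, and not each list, apart from chance in that setting only. In all 3 comparisons most of the other splits also called some list. An adjusted p under 0.05 from camera at the preset correlation therefore does not by itself set a list apart from chance. The 2 genes changed back were matched by 1 of 100 splits, the real one (highest other 1). For KO AAV against WT saline 4 of 100 splits gave as many as its 1 gene, Grn (highest other 5), and for its 0 lists all 100 did, as any count must (highest other 7).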

How the results depend on the processing

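Chosen after seeing the data were the refined counts, thinning, both principal component terms, the GC correction, males only, sex as a term for lists, and the split of KO saline; the other settings were planned. Results that answer a comparison had 390 values under alternatives: 331 kept their side of the threshold (or stayed within 1.5 times, for counts), 28 were lower, 31 higher and 0 reversed. Among other named genes, 5514 values gained a call in 10 cases (of Ctss, Fam171a2, Ctsc and Lyz2), differed in sign in 144 and reversed a call in 0. The cause was not tested unless stated, and depth limits calls on genes below the filter.

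Genes are given in the order KO saline against WT saline, KO AAV against KO saline, KO AAV against WT saline, changed back. With no count filter they were 16, 4, 2 and 4 (24497 genes tested, and Xist among them follows the sex balance). The fit changed there as well as the adjustment. In KO saline against WT saline Fam171a2 then had an adjusted p of 1.65e-04, below its unadjusted p of 0.0109 in the main edgeR fit. With mean CPM of at least 5, KO AAV against KO saline had 1 and changed back 1, since Clec7a is then not tested; without the 2 libraries of RIN 8.0, and with thinned libraries, both were again 1. With limma on log2(deposited CPM + 0.25) both were 0 (283 genes unadjusted; DESeq2 gave 3 and limma-voom 2). Males only, fewer animals, gave 2, 0 (385 unadjusted) and 0 changed back. With the first residual component as a term KO AAV against KO saline had 4 and KO AAV against WT saline 33. That component by construction does not differ between groups and takes up spread within them, though fitted group differences can shift. With the first component of all libraries the counts were 3 and 1.

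Lists were 11 in KO saline against WT saline with males only. In KO AAV against KO saline they were 3 with an estimated correlation and 5 by fry (disease-associated microglia, complement and reactive astrocyte lower, oligodendrocyte precursor and iron higher). In KO AAV against WT saline they were 2 by fry, 1 with mean CPM of at least 5, 1 with thinned libraries, 1 with the first principal component as a term, 2 with the GC trend removed and 4 with males only. The disease-associated microglia score of KO AAV against WT saline passed without lysosome members (0.14, exact p = 0.0325), thinned (0.14, exact p = 0.0195) and with the GC trend removed (0.13, exact p = 0.0325). Called genes near Grn were 1 within 10 Mb (exact p = 0.0700) and 0 for KO AAV against WT saline. Recovery stayed between 0.718 without a split and 0.821 at an adjusted p under 0.2.

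Whether replicate numbers pair the animals was not settled: correlations of same-numbered libraries ran from -0.431 to 0.444, 5 of 15 above 0.1. Sex was the same within replicates 1, 2, 3 and 5, and age within replicates 1 and 2, so a pairing is not excluded. With the replicate number as a block the genes were 3, 0 (221 unadjusted) and 0 changed back, the calls ended being those of Ctss and Lyz2 in the first and of Clec7a and Gfap in the second. The log2 changes were 0.62, 1.82, -3.01 and -1.18 (adjusted p from 0.0512 to 0.0882), so the effects were about as large. Permutation inside the block gave scores of 0.46 and -0.30 (p = 0.0625 each, the smallest those flips allow).

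Leaving out 1 library gave 4 to 5, 1 to 2 and 1 to 1 genes, 1 to 2 changed back, and Grn bounds of -5.78 to -5.26 and -6.06 to -5.59. Gfap was the call lost in KO AAV against KO saline, without KO AAV replicate 1, 3 or 4 or KO saline replicate 4. Lists ran from 5 to 11 (11 without WT saline replicate 4, 10 without KO saline replicate 2), 7 to 11, and 0 to 6 (6 without WT saline replicate 2, 3 without 4, 1 without KO AAV replicate 2 or 3). Scores ran from 0.40 to 0.46, -0.32 to -0.26 and 0.11 to 0.17, the last passing in 9 of 16.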

Other observations

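The genes and lists of this part were picked from fixed lists after the values were seen, and no explanation is offered for them. In KO saline against WT saline, Cd33, a sialic acid receptor of microglia, was at 0.84 (SE 0.21) and passed when adjusted over the list alone among 24 homeostatic microglia markers, 15 of which were positive. P2ry12 at 0.28 (SE 0.15) and Tmem119 at 0.17 (SE 0.30), markers of resting microglia, did not pass. Slc40a1, the iron exporter ferroportin, was at 0.91 (SE 0.27) and passed when adjusted over the list alone among 13 iron and transferrin receptor genes, a list that did not pass (camera adjusted p = 0.743). Over all genes the adjusted p of Cd33 and Slc40a1 were 0.688 and 0.994. The water channel gene Aqp4 of astrocyte end-feet was at 0.20 (SE 0.16).

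In KO AAV against WT saline, Mvd, an enzyme gene of cholesterol synthesis, was at -0.51 (SE 0.15) and passed when adjusted over the list alone; the 22 cholesterol genes, 16 of them negative, did not (camera adjusted p = 0.120). Syp, the synaptophysin gene, was at -0.49 (SE 0.14) there, and 36 synapse genes did not pass (0.655; 18 positive, 18 negative). Vacuolar ATPase genes, of the proton pump of lysosomes, were negative in 12 of 17 (0.129). Progranulin partners and frontotemporal dementia genes had adjusted p of 0.612, 0.714 and 0.406 in the 3 comparisons, and Tmem106b, a lysosomal membrane protein gene among them, was at 0.01 (SE 0.15), 0.20 (SE 0.16) and 0.21 (SE 0.15).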
